A study of Mus musculus with 12 samples.

How the data were processed

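Livers of 12 mice were analysed, each on its own Affymetrix transcriptome array. Per the labels, mice of the C57BL6/J strain were killed at 12 weeks, the liver was snap frozen, total RNA was extracted with Trizol, and the product was fragmented and biotinylated with a terminal labelling kit. Mice were grouped by the genotype in the labels and by the letter for sex in each title, which was read together with the statement that the groups were matched for gender. The 4 groups (WT male, WT female, KO male, KO female) hold 3 mice each, and replicates are named by the animal number in the title. No number occurs in more than 1 group, so nothing pairs the mice. Litter, housing, time of death and array batch are not given in the sources used here.

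The values are the deposited log2 signals per feature. They were made with Transcriptome Analysis Console, per the submitters' processing notes, which give no version; background correction, normalization, summarisation, probe annotation and genome build are not given in the sources used here. Array medians lay within 3.76 to 3.89, higher by 0.07 in KO (exact permutation p = 0.015), and every array shared a ceiling at 19.93. The arrays had therefore been brought near a common scale before they were deposited. That ceiling exceeds 16, the largest log2 value of a 16-bit scanner, so the intensities were stretched by a step that is not named, and fold differences are those of the deposited scale. A gene at the ceiling has only a lower bound. Detection calls were not used here, and no feature was left out for low signal in the main test.

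The table holds 72688 features. The 6732 control features were kept out of all tests: 5222 negative, 1324 positive and 23 background controls, 92 external RNA controls, 63 features for the dilution steps of their mixes, 4 poly-A spikes and 4 hybridisation spikes. All but the 63 were used to compare arrays. Gene symbols came from a table pairing the features with platform annotation. Of the 65956 transcript features 31258 had 1 symbol, 1492 had several and 33206 had none; features with several symbols were tested but, apart from those of adult haemoglobin genes, not named. The named features cover 30702 genes, of which 30700 were found in the RefSeq gene table of the GRCm38.p6 assembly. That table was used for gene class and for neighbouring genes only, and no coordinates are printed, because the build behind the array annotation is not given. Ddx3y had no feature with its own symbol and is not analysed here.

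A model of 4 group means was fitted to the log2 values of all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups shared 1 estimate of the spread, with 8 residual degrees of freedom. Contrasts were KO minus WT averaged over the sexes, KO minus WT within each sex, the difference between these, and female minus male averaged over the genotypes. P-values were adjusted by Benjamini-Hochberg (BH) over all 65956 features, with a threshold of 0.05. Where a gene is named, its value is that of the feature with the highest mean signal. A named gene was set against the negative controls by whether all 3 mice of a group lay at or below their 95th percentile on the same array. Array-level measures were compared by exact permutation of genotype within sex (400 arrangements, two-sided).

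Before the data were examined, 38 gene lists were written down for pathways, sex bias and cell types of the liver and neighbouring tissues, and 37 had at least 5 measured members. They hold 1204 entries, of which 1042 had a feature of their own. Lists were tested with camera, preset correlation 0.01, on 1 feature per gene and adjusted over the lists; camera with an estimated correlation and fry were run beside it. Counts "over the list alone" come from BH adjustment within the list. Slc29a3 is in no list.

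The genes named were fixed by a rule written at the same time: Slc29a3; the 12 largest differences in each direction among genes passing the test over both sexes; the 5 largest in each direction within each sex and for the interaction, filled by the smallest unadjusted p at 1.5-fold or more where fewer pass; Xist, Ddx3y, Kdm5d, Eif2s3y, Uty and the 5 largest autosomal differences in each direction between the sexes; and for each list up to 4 members with the smallest unadjusted p, or the 2 of highest signal where none was under 0.05. Predicted, RIKEN, small RNA, pseudogene and olfactory or vomeronasal entries were left out. Genes outside this rule are marked as chosen after their values were seen.

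The fit was tested on simulated data with the spread of the real arrays. For KO against WT over 65956 features, 50 features changed by each of 0.5, 1, 2 and 4 on the log2 scale were recovered at 60%, 86%, 100% and 100%, with 12 false calls. For the list test, a list raised by 0.5 was called and 0 of the other lists were. Simulated noise was independent between features, so this does not show how often lists of correlated genes are called falsely.

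Alternatives fixed beforehand were quantile normalization, median centring, a filter on dim features, an intensity trend with robust variance, array weights, leaving out each mouse, no sex term, the arrays of 1 sex alone, 1 feature per gene, a 1.5-fold requirement, an estimated correlation and the mean of all features of a gene. Chosen after seeing the data were the mean of the 4 poly-A spikes as a covariate, protein-coding genes alone, leaving out features at the ceiling, and leaving out KO male 19 and WT female 38. On the first principal component these were the KO mouse nearest the WT mice and the WT female nearest the WT males; WT female 25, the WT mouse nearest the KO mice, was kept. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.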

Results

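Liver gene expression was measured in 12 mice aged 12 weeks, 6 wild-type (WT) and 6 knockout (KO) for ENT3, with 3 males and 3 females of each genotype. ENT3 is the equilibrative nucleoside transporter encoded by Slc29a3 and is located mainly in lysosomal and mitochondrial membranes. Each liver was hybridised to its own array, and 65956 transcript features were tested. Array medians lay between 3.76 and 3.89 on the deposited log2 scale. Arrays of the same group correlated at r = 0.987 to 0.995 across features, which are not independent replicates. Every array had the same highest value, 19.93, reached by 172 features on all 12 arrays, so that genes at that ceiling, among them Alb, could not show a difference. The number of arrays sets the precision here, and differences are log2 differences of KO minus WT with the standard error (SE) of the limma fit to 6 mice per genotype.

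The targeted gene was examined first. Slc29a3 averaged 4.13 ± 0.04 (SD, n = 6) in KO livers and 5.07 ± 0.18 (SD, n = 6) in WT livers. All 6 KO values, 4.10 to 4.19, lay below all 6 WT values, 4.82 to 5.29, and the difference was -0.94 ± 0.07 (limma adjusted p = 0.000324). The KO level was close to the array medians, and both genotypes lay within the range of the negative control features, whose 95th percentile was 6.20 to 6.83 on the 12 arrays, so the size of the difference is not exact. It was lower in both sexes, by -1.05 in females (adjusted p = 0.0012) and -0.83 in males (adjusted p = 0.00847). The labels do not say which part of the gene was removed, so the position of the probes relative to it is not given in the sources used here. With the poly-A spike level as a covariate, an alternative chosen after seeing the data, the difference was -0.80 ± 0.18 and was no longer called (adjusted p = 0.222).

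**Figure D1:**
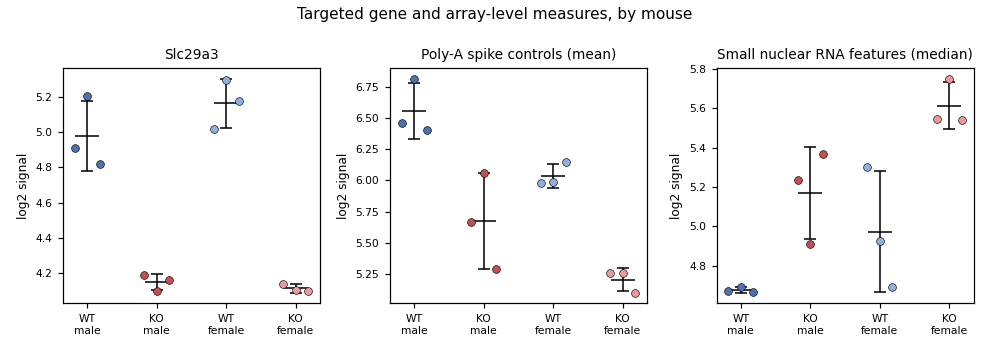
Log2 signal of Slc29a3 (left), mean log2 signal of the 4 poly-A spike controls (middle) and median log2 signal of 927 small nuclear RNA features (right) for each mouse, by genotype and sex. Points are mice, horizontal marks are group means and bars are SD (n = 3 per group); Slc29a3 lay between 4.10 and 4.19 in KO mice and between 4.82 and 5.29 in WT mice.

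Several array-level measures differed between genotypes. The poly-A spikes, bacterial transcripts added to the RNA before labelling, averaged 5.44 ± 0.36 (SD, n = 6) in KO and 6.30 ± 0.32 (SD, n = 6) in WT arrays (exact permutation within sex, two-sided p = 0.005, the smallest that 400 arrangements can give, BH p = 0.02 over 12 measures). Positive control features had a lower median in KO, 8.12 against 8.51 (exact permutation p = 0.01, BH p = 0.024). Negative control features had a median higher by 0.14 in KO (exact permutation p = 0.005, BH p = 0.02). The median of all transcript features was higher in KO by 0.07 (exact permutation p = 0.015, BH p = 0.03), and that of protein-coding features by 0.06 (exact permutation p = 0.01, BH p = 0.024). Hybridisation spikes, added after labelling, differed by -0.09 (exact permutation p = 0.395). These differences stand beside every gene group below. The poly-A spikes were lower in KO in both sexes, at 5.21 in KO females, 6.04 in WT females, 5.67 in KO males and 6.56 in WT males.

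Genotype was compared over both sexes to ask what loss of the transporter does to liver expression. Among called genes, the largest rises in KO livers were in S100a8 and S100a9, calcium-binding proteins abundant in neutrophils and monocytes. S100a8 and S100a9 had log2 differences of 8.30 ± 1.02 and 7.73 ± 1.02, which ran from 7.40 to 9.28 and from 6.83 to 8.70 when any 1 mouse was left out. Next came Tff3, a trefoil factor of mucous epithelia (6.51), Fcgr4, an Fc receptor for IgG (6.47), Cxcl13, a B cell chemokine (6.32), and Marco, a macrophage scavenger receptor (6.27). Fcer1g, the shared signalling chain of Fc receptors, differed by 4.86, Igfbp1, a secreted binding protein of insulin-like growth factors, by 4.63 and Retnlg, a resistin-like peptide of neutrophils, by 4.58. The mitochondrial tRNA gene mt-Tk (4.42) and the myeloid lectins Clec4a3 (4.41) and Clec4a1 (4.35) completed the 12 largest rises among called genes. KO female 69 was at the ceiling for mt-Tk, so the printed difference and rank of mt-Tk are not exact.

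**Figure D2:**
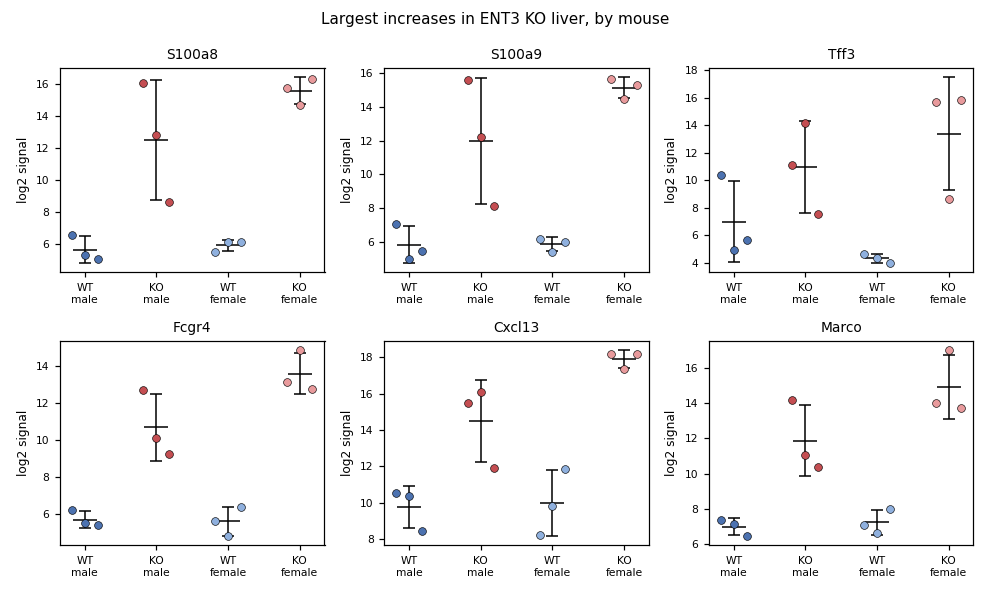
Log2 signal of the 6 genes with the largest rise in KO liver for each mouse, by genotype and sex, with group means and SD (n = 3 per group). S100a8 ranged from 8.59 to 16.3 in KO mice and from 5.004 to 6.57 in WT mice, and the KO males were spread more widely than the KO females for this gene.

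Among falls, Sult2a8, a sulfotransferase acting on bile acids, fell by 5.002 ± 0.898 on the log2 scale, Car3, a cytosolic carbonic anhydrase, fell by 4.82 ± 0.67, and Vnn1, a pantetheinase induced by PPAR alpha, fell by 4.62 ± 0.86. Retsat, a retinol saturase (-4.10), Aldh3a2, a fatty aldehyde dehydrogenase (-3.80), Inhbe, the beta E subunit of activin (-3.64), Acaa1b, a peroxisomal thiolase (-3.64), and Slc2a2, the hepatic glucose transporter (-3.62), followed. The last of the 12 were Acot2, a mitochondrial acyl-CoA thioesterase (-3.49), Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase (-3.47), Fabp2, a fatty acid binding protein (-3.44), and Hsd3b3, a steroid dehydrogenase (-3.40). Adjusted p over these 24 genes ran from 0.000532 to 0.0274. In all 24, each of the 6 KO mice lay beyond the WT mean of its own sex. Every KO mouse lay above every WT mouse in 10 of the 12 rises, and below every WT mouse in only 5 of the 12 falls. The 24 genes were picked by the size of their differences, which are averages over the sexes. Slc2a2 was at -5.83 in females and -1.40 in males, Sult2a8 at -7.39 and -2.61, and mt-Tk at 6.71 and 2.13. None of these passed in males (limma adjusted p = 0.432, 0.436 and 0.198) or for the interaction (limma adjusted p = 0.344, 0.667 and 0.321). Of the 24, only Inhbe (-2.90 and -4.39) and Acot2 (-3.08 and -3.90) differed more in males. Of the 190 genes named by rule, 87 had at least 1 group of 3 mice within the 95th percentile of the negative controls. Among them were S100a8, S100a9, Tff3, Fcgr4, Retnlg, Clec4a3 and Clec4a1 in WT mice of at least 1 sex, so the sizes printed for these are not exact. In 32 of the 87 every group lay there, including Saa3, Tnfaip3, Ccn2, Jchain, Rps9, Uros, Ccne1, Procr, Klf11, Nfil3 and Kdm5d, named below. The sizes of these are not exact either, and the negative control median was itself higher by 0.14 in KO.

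**Figure D3:**
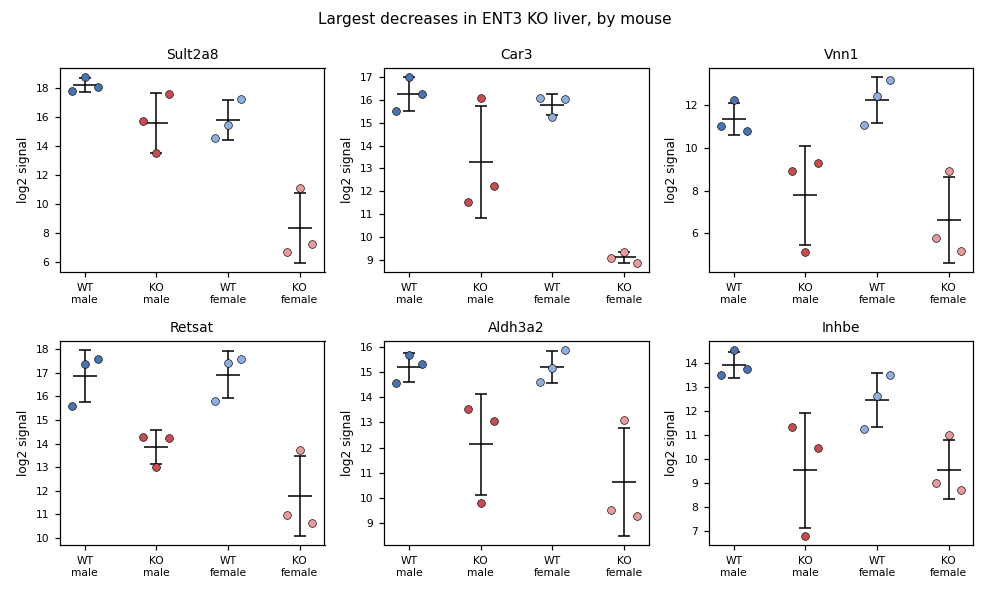
Log2 signal of the 6 genes with the largest fall in KO liver for each mouse, by genotype and sex, with group means and SD (n = 3 per group). Car3 ranged from 8.88 to 16.1 in KO mice and from 15.2 to 16.97 in WT mice.

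Counted over the array, 6432 of 65956 features passed the limma test at an adjusted p under 0.05, 3482 higher and 2950 lower in KO. By gene, 4317 of 30702 were called, 1783 higher and 2534 lower. Scaling changed the split of features between directions: after quantile normalization 2555 were higher and 4091 lower, and with each array centred on its median 2538 were higher and 4001 lower. With a 1.5-fold difference also required 3661 features were called. With the poly-A spike level as a covariate, chosen after seeing the data, 3 were called; that level differs between the genotypes, and 158 of the 159 called named genes kept their sign. Among protein-coding genes alone 1336 were higher and 2582 lower. With the poly-A covariate Car3 was at -1.18 ± 1.15, Cxcl13 at 10.65 ± 1.44 and Fabp2 at -6.11 ± 1.86. Among the 24 genes, Tff3 lost its call without any one of WT males 23 and 33, WT females 27 and 38, KO males 18 and 19 and KO females 13 and 69 (adjusted p up to 0.0697). Fabp2 lost it without any one of WT males 17 and 23, WT females 25 and 38 and KO females 13 and 69 (up to 0.061), and Acaa1b without WT female 38 (0.0514). With no sex term, the adjusted p was 0.115 for Sult2a8, 0.0783 for Slc2a2 and 0.0869 for mt-Tk. Without KO male 19 and WT female 38, chosen after seeing the data, 4746 features were called, Igfbp1 had an adjusted p of 0.0511, Tff3 of 0.104 and Fabp2 of 0.0625.

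Among the cell-type lists, those of macrophages and of neutrophils had the largest median shifts. Of 32 measured genes of Kupffer cells and macrophages, 22 rose, 1 fell and 9 did not pass (27 and 1 when adjusted over the list alone), with a median difference of 1.83. Fcgr4 (6.47 ± 0.59), Marco (6.27 ± 0.73) and Fcer1g (4.86 ± 0.50) rose, whereas Cd163, the haptoglobin-haemoglobin scavenger receptor, fell by 1.74 ± 0.19. Of 17 neutrophil and granulocyte genes, 11 rose and none fell (16 over the list alone), among them Il1r2, a decoy receptor for interleukin 1 (0.85 ± 0.12), whose signal lay within the range of the negative controls in every group. Of 10 megakaryocyte and platelet genes, 4 rose (6 over the list alone), including the integrin Itgb3 (0.96 ± 0.14) and the lectin Clec1b (1.81 ± 0.35). The competitive camera test with a preset correlation called the 3 lists (adjusted p = 2.14e-12, 1.31e-08 and 0.000128). None held with an estimated correlation (adjusted p = 0.26 for each). fry, which asks whether the genes of a list move in one direction, gave adjusted p = 0.00292, 0.00319 and 0.00292.

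Of 39 genes of Toll-like receptor, NF-kB and cytokine signalling, 16 rose and none fell (26 over the list alone). Vcam1, an adhesion molecule for leukocytes, rose by 3.77 ± 0.41, Irak3, an inhibitor of Toll-like receptor signalling, by 2.35 ± 0.29, the NF-kB inhibitor Tnfaip3 by 0.89 ± 0.12. Tnf passed at 0.40 ± 0.05, but its WT mean, 3.71, lay below the WT mean of the negative control medians, 3.797, so its size is not exact. Signal of Tnfaip3, and of Saa3 named below, lay within the range of the negative controls in every group, so these sizes are not exact either. The list was called by camera (adjusted p = 6.19e-10) but not with an estimated correlation (adjusted p = 0.145). Of 32 acute phase genes, 6 rose (10 over the list alone), with Saa3 at 1.02 ± 0.16 and Steap4, a metalloreductase, at 2.94 ± 0.65, and 6 of the 32 lay at the ceiling on every array. The acute phase list had a camera adjusted p of 0.0083, of 0.457 with an estimated correlation, of 0.135 with the poly-A covariate and a fry adjusted p of 0.0577. In the interferon response list 3 of 46 genes fell (6 lower and 1 higher over the list alone). Usp18, a protease induced by interferon, differed by -1.62 ± 0.40 and lost its call in 8 of 12 fits that left out 1 mouse. The other 2, Ifi35 and Irf9, lost theirs in 8 and 9. That list was not called (camera adjusted p = 0.752), and its median, 0.09, was positive while camera's direction was down; with the poly-A covariate it was called as lower (0.0314). Poly-A spike signal was lower by 0.86 in the same KO arrays.

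Fatty acid oxidation genes fell most broadly among the metabolic lists. Of 40 genes of fatty acid oxidation and PPAR alpha targets, 31 fell, none rose and 9 did not pass (36 over the list alone), with a median of -1.38. Eci1 and Decr2, auxiliary enzymes for unsaturated fatty acids, differed by -2.57 ± 0.31 and -2.38 ± 0.30. Ech1, an isomerase of the same pathway, differed by -2.00 ± 0.21 and Creb3l3, a transcription factor of fasting lipid metabolism, by -0.72 ± 0.07. In the list of fatty acid and triglyceride synthesis 8 of 33 fell and none rose (11 over the list alone), with the desaturase Fads2 at -2.87 ± 0.37, the elongase Elovl6 at -1.97 ± 0.16 and the acyltransferase Gpam at -1.62 ± 0.25. With the poly-A covariate Ech1 was at -1.20, Fads2 at -4.52 and Gpam at -2.59. Camera called both lists (adjusted p = 2.00e-21 and 0.000228) and neither with an estimated correlation (adjusted p = 0.145 for each); the synthesis list was not called with the poly-A covariate (adjusted p = 0.253). Of 19 cholesterol genes, Sc5d, a sterol desaturase, was the 1 that fell (-1.16 ± 0.16; 0.055 with no sex term), and the list was not called (camera adjusted p = 0.752), but was called as higher with the poly-A covariate (0.00688).

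Nuclear genes of oxidative phosphorylation shifted by a smaller amount. Of 48, 24 fell and 1 rose (32 and 1 over the list alone), with a median of -0.41. The complex I subunits Ndufs8 and Ndufb5 differed by -1.41 ± 0.16 and -0.44 ± 0.05, Sdhd of complex II by -1.34 ± 0.16 and Uqcrc2 of complex III by -0.76 ± 0.11. With the poly-A covariate Ndufs8 was at -0.78, Sdhd at -0.76 and Uqcrc2 at -0.16. Camera called the list (adjusted p = 6.42e-14), but not with an estimated correlation (adjusted p = 0.145) or with the poly-A covariate (adjusted p = 0.129). The list of mitochondrially encoded genes was not tested: its ribosomal RNA mt-Rnr1 was at the ceiling on every array, and its 1 other match, Gm10925, came through a synonym and has a feature on chromosome 1. The mitochondrial tRNA gene mt-Tk is not in that list. In the list of glycolysis, gluconeogenesis and glycogen 7 of 33 fell and 1 rose (10 and 6 over the list alone), with Ugp2, which makes UDP-glucose, at -1.32 ± 0.15, and the list was not called (camera adjusted p = 0.0807), but was without WT female 25 (0.0395) or KO male 19 (0.0367).

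Part of the bile acid and xenobiotic genes fell. Of 35 genes of bile acid synthesis and transport, 15 fell and 2 rose (24 and 2 over the list alone). The basolateral uptake transporters Slco1b2 and Slc10a1 differed by -1.75 ± 0.27 and -1.16 ± 0.18, and the conjugating enzyme Baat by -0.86 ± 0.14. Slco1b2 was at -2.92 in females and -0.57 in males (male adjusted p = 0.619), and Slc10a1 at -2.43 and 0.11 (male adjusted p = 0.925). With no sex term Slco1b2, Slc10a1 and Baat were not called (adjusted p = 0.0878, 0.242 and 0.238). Of 45 cytochrome P450 and other xenobiotic genes, 14 fell and none rose (20 lower and 1 higher over the list alone), including Ugt2b34 (-2.02 ± 0.21), Cyp2j5 (-1.70 ± 0.18) and the nuclear receptor Nr1i2 (-1.41 ± 0.17). The xenobiotic median was -1.08 in females and -0.13 in males, where camera did not call the list (adjusted p = 0.102). Of 35 NRF2 and glutathione genes, 11 fell and 2 rose (13 and 2 over the list alone): Gclc, which catalyses the first step of glutathione synthesis, was at -2.52 ± 0.39 and Hmox1, haem oxygenase, at 3.44 ± 0.55. Camera adjusted p for the 3 lists was 4.54e-08, 1.77e-08 and 0.000705, and with an estimated correlation none was called (adjusted p = 0.145, 0.145 and 0.285). The NRF2 list was not called with the poly-A covariate (adjusted p = 0.981).

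Zonal and sex-biased hepatocyte genes were tested as separate lists. Of 16 pericentral genes 6 fell and 1 rose (10 and 1 over the list alone), with Cyp2c37 at -1.70 ± 0.23 and the calcium-binding protein Rgn at -0.94 ± 0.18. The pericentral median was -1.25 in females and -0.25 in males, where camera did not call the list (adjusted p = 0.2). Of 18 periportal genes 5 fell and 1 rose (6 and 1 over the list alone), with the immunoglobulin receptor Pigr at -0.81 ± 0.12 and the lysosomal protease Ctsc, also expressed in leukocytes, at 1.52 ± 0.20. The pericentral list was called by camera (adjusted p = 0.000198) but not with an estimated correlation (adjusted p = 0.145) or the poly-A covariate (adjusted p = 0.0578), and the periportal list was not called (adjusted p = 0.0807), but was without WT male 23 (0.0308) or KO female 13 (0.0489). Of 34 male-biased genes 11 fell and 1 rose (16 and 2 over the list alone), among them Hsd3b2 at -1.83 ± 0.26 and Keg1 at -1.69 ± 0.23 (camera adjusted p = 7.00e-06, 0.145 with an estimated correlation). Of 31 female-biased genes 4 fell (6 over the list alone), among them Cyp2c69 at -1.59 ± 0.20 and Cyp2c40 at -1.26 ± 0.17. The largest fall of the 4 was that of Acot3, at -2.70 ± 0.58 (limma adjusted p = 0.017). KO signal of Acot3 lay within the range of the negative controls, so its size is not exact. Cyp2c69 was at -3.10 in females and -0.09 in males (male adjusted p = 0.953), and Cyp2c40 at -2.31 and -0.20 (male adjusted p = 0.819). Both were higher in every WT female than in every WT male, Cyp2c69 at 16.3 to 17.3 against 15.4 to 15.6. That list had a camera adjusted p of 0.0164, of 0.307 with an estimated correlation, of 0.121 with the poly-A covariate of 0.192 after quantile normalization and of 0.103 without KO female 40. With no sex term adjusted p was 0.0802 for Cyp2c37, 0.0547 for Ctsc, 0.0815 for Hsd3b2, 0.16 for Keg1, 0.0714 for Cyp2c69 and 0.0585 for Cyp2c40, and with the poly-A covariate Cyp2c37 was at -1.06, Cyp2c40 at -0.83 and Cebpa at -1.90. Of 25 core hepatocyte genes 15 lay at the ceiling on every array; 3 fell, among them Otc of the urea cycle (-1.19 ± 0.18) and the transcription factor Cebpa (-1.13 ± 0.21), and the count was 3 over the list alone. The core list was not called (camera adjusted p = 0.0807), but was with each array centred on its median (0.00148) and without features at the ceiling (0.00697).

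Lists close to the function of the transporter were mixed. Of 47 lysosomal genes 8 fell and 4 rose (13 and 7 over the list alone): Tpp1, a lysosomal peptidase, was at -1.15 ± 0.14, the sulfatase Arsb at -0.64 ± 0.06 and Ctss, a cathepsin of antigen-presenting cells, at 3.96 ± 0.60. The list was not called (camera adjusted p = 0.0843), its median was -0.08 and its mean 0.02. Leaving out WT female 25 or KO male 19 gave an adjusted p of 0.0221 or 0.029 with lower expression, and the poly-A covariate turned it to higher expression (0.0222), with Tpp1 at -0.46. Of 45 genes of nucleoside transport and nucleotide metabolism 7 fell and 1 rose (10 and 3 over the list alone), with Paics and Ppat of purine synthesis at -1.51 ± 0.11 and -0.69 ± 0.12 (Ppat 0.0969 with no sex term), Dpys of pyrimidine breakdown at -1.46 ± 0.25 and xanthine dehydrogenase, Xdh, at 1.10 ± 0.15. This list was not called (camera adjusted p = 0.0761), but had an adjusted p of 0.0395, 0.0454 and 0.0485 without WT female 25, WT female 27 or KO male 18. Of 35 autophagy genes 10 fell and none rose (12 lower and 1 higher over the list alone), with Gabarapl1 at -1.60 ± 0.25 and Atg4b at -0.39 ± 0.07; camera gave an adjusted p of 0.000408, 0.285 with an estimated correlation and 0.45, in the opposite direction, with the poly-A covariate, where Atg4b was at -0.22.

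Markers of other cell types were tested as separate lists. None of 20 T and NK cell genes passed (0 over the list alone), and Ccl5 was at 1.28 ± 0.37 (adjusted p = 0.0588). Of 15 B and plasma cell genes 3 rose (3 over the list alone), including Ighm (2.39 ± 0.38) and Jchain (0.90 ± 0.19), and of 304 immunoglobulin and T cell receptor segment features 60 were higher and 0 lower in KO. Of 23 stellate cell and fibrosis genes 3 rose (3 over the list alone), with vimentin, Vim, at 1.79 ± 0.33 and Ccn2 at 0.59 ± 0.09. Of 20 endothelial genes 3 rose and 4 fell (4 and 10 over the list alone): Pecam1 (1.14 ± 0.16) and Cdh5 (0.76 ± 0.13) rose, while Clec4g (-1.46 ± 0.26) and Kdr (-0.63 ± 0.10) fell; with no sex term Cdh5 (0.154) and Kdr (0.0586) did not pass, and with the poly-A covariate Cdh5 was at 1.30. Adult haemoglobin features, which carry several symbols and were chosen after their values were seen, were at 2.66, 2.11, 1.52 and 0.77, and 3 of the 4 passed (adjusted p = 0.0153, 0.0206, 0.0398 and 0.0698). Of 12 erythroid genes, 10 of them with a group in the range of the negative controls, the haem enzyme Fech fell (-0.99 ± 0.12) and none rose, and of 13 bile duct genes Krt8 fell (-1.08 ± 0.23; 0.0593 without KO male 19 and WT female 38, and -1.78 with the poly-A covariate) and none rose (2 lower over each list alone). None of 19 genes of pancreas, fat, muscle and gallbladder passed. Camera called the endothelial list as lower (adjusted p = 0.0264, 0.338 with an estimated correlation, 0.185 after quantile normalization, 0.0517 without KO male 39) and none of the others, with adjusted p = 0.188 for T and NK cells, 0.226 for B cells, 0.188 for stellate cells, 0.613 for erythroid cells, 0.598 for bile duct cells and 0.0807 for neighbouring tissues. The neighbouring tissue list was called as lower without WT female 38 (adjusted p = 4.05e-06) or KO female 40 (0.0385).

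**Figure D4:**
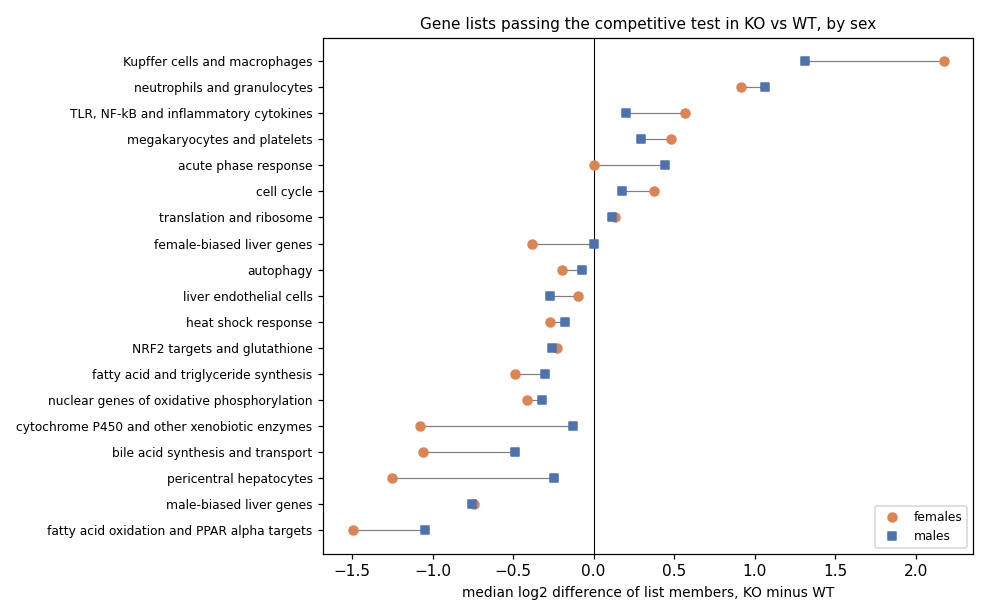
Median log2 difference (KO minus WT) of the members of each of the 19 lists that passed the competitive test with a preset correlation, in females (circles) and males (squares). The Kupffer cell and macrophage median was 2.18 in females and 1.31 in males, and the fatty acid oxidation median was -1.49 and -1.05.

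Over all 37 lists tested, 19 passed with the preset correlation, 7 higher and 12 lower, and 0 passed with an estimated correlation (adjusted p from 0.145 to 0.51 over those 19). fry, which does not set a list against the other genes, called 19 lists, 15 of them among the 19 that camera called. The others that camera called were the cell cycle (fry adjusted p = 0.0618), acute phase (0.0577), translation (0.0545) and endothelial (0.0577) lists.

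Within females, 3 KO were compared with 3 WT mice. Among genes that passed, S100a8 (9.71), S100a9 (9.29), Tff3 (9.05), Fcgr4 (7.97) and Cxcl13 (7.91) rose most. The largest falls were in the sulfotransferases Sult3a1 (-8.18), Sult3a2 (-7.67) and Sult2a8 (-7.39), in Car3 (-6.67) and in Cyp7a1 (-5.89), the rate-limiting enzyme of bile acid synthesis. Among all features 4083 passed, 2064 higher and 2019 lower (1592 and 2501 after quantile normalization, 1466 and 2913 with each array centred on its median, 1108 and 2027 among protein-coding genes, 935 and 1534 without WT female 27). The call of Cyp7a1 was lost in 6 of 12 fits that left out 1 mouse, while Sult3a1 and Sult3a2 kept theirs. The other genes named here for females were refitted without each mouse over both sexes only. Their female calls were not checked in this way. The count was 2469, 1581, 2503 and 2127 without WT female 27, WT female 38, KO female 13 or KO female 69, 1853 with the female arrays fitted alone and 74 with the poly-A covariate.

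In males fewer features passed, 716, of which 382 were higher and 334 lower (446 and 643 after quantile normalization, 42 and 366 among protein-coding genes, 646 and 292 without KO male 19, 115 and 66 without KO male 18). Among genes that passed in males, the largest rises were in Fcgr4 (4.97), the leukocyte integrin Itgb2 (3.31), Vcam1 (2.99), the lectin Cd207 (2.81) and Spic (2.42), a transcription factor of red pulp macrophages. The largest falls among those that passed were in the elongase Elovl3 (-4.81), the clock repressor Nr1d1 (-3.57), Gpd1 (-2.70), the kinase Sgk2 (-2.54) and the P450 enzyme Cyp2c23 (-2.47). Larger male differences that did not pass include S100a8 at 6.89 (adjusted p = 0.0594), S100a9 at 6.17 (0.0858), Inhbe at -4.39 (0.1) and Acot2 at -3.90 (0.0643). Limma adjusted p for the 10 genes that passed lay between 0.00847 and 0.0456, the largest being that of Vcam1. Itgb2 lost its call in 10, Elovl3 in 9, Spic in 5 and Sgk2 in 3 of 12 fits that left out 1 mouse. Cd207 and Cyp2c23 kept theirs. Fcgr4, Vcam1, Nr1d1 and Gpd1 were refitted without each mouse over both sexes only, so their male calls were not checked in this way. The count was 303, 161, 248, 181 and 418 without WT male 17, 23 or 33 or KO male 18 or 39, and 367 and 379 without KO female 13 or 69, whose arrays share the estimate of the spread. It was 37 with the male arrays fitted alone and 0 with the poly-A covariate, where 716 features and 8452 at an unadjusted p under 0.05 had passed without it.

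The test of the difference between the sexes called 1 feature by limma, and 4396 had an unadjusted p under 0.05. That feature, of the small nuclear RNA gene Rnu1b1, was at the ceiling in 9 of 12 arrays, among them all 6 female arrays, so its female difference and its interaction are unknown; it is named because it was the only call. No gene passed by its representative feature. Those with the smallest unadjusted p and at least a 1.5-fold difference included the P450 gene Cyp2c67, which differed by -3.15 in females and -0.59 in males (interaction -2.56, adjusted p = 0.0554), and the retinol dehydrogenase Rdh7 (-1.11, adjusted p = 0.0711). Klf11 was at 0.48 in females and -0.47 in males, and the small heat shock gene Hspb8 at 1.03 and -0.77 (adjusted p = 0.0554 and 0.0608). Signal of Klf11 lay within the range of the negative controls in every group, so its sizes are not exact. Nor did the sulfotransferases pass this test: Sult3a1 was at -8.18 in females and 1.87 in males, with an interaction of -10.05 (limma adjusted p = 0.246). WT male signal of Sult3a1 lay within the range of the negative controls, so a fall in males could hardly have been seen. With each array centred on its median Cyp2c67 passed. The count was 42, 55, 35 and 16 without WT female 38, KO female 40, KO male 19 or WT male 33, 3 without WT male 17 or KO male 18, and 0 without WT female 27, KO male 39, KO female 13 or KO female 69.

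Of the 4317 genes called over both sexes, the difference was larger in females for 3321. The median ratio of the male to the female difference was 0.682. Genes called in both sexes in the same direction numbered 331, of which 83 were higher and 248 lower, against 8.03 and 16.5 from independent lists. The female and male lists are not independent, as they share the estimate of the spread and array-level differences between genotypes. These counts are therefore no test of a shared effect.

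Females and males were compared over both genotypes as a check of the sex labels. Xist, the X inactivation transcript, was higher in females by 7.37 ± 0.27 (adjusted p = 2.26e-06), and the Y-linked genes Eif2s3y (-2.95), Uty (-2.21) and Kdm5d (-1.10) were lower. Among autosomal genes that passed, Sult2a1 (10.94), Sult2a2 (10.05), the transporter Slc22a26 (6.49), Sult3a1 (6.24) and Sult2a5 (5.96) were higher in females. Cyp4a12b (-9.01), Cyp4a12a (-8.72), Cyp2d9 (-5.44), the transporter Slco1a1 (-4.86) and Sult2a8 (-4.82) were higher in males. Sult3a1 separated the sexes in WT mice only, at 13.9 to 17.3 in females and 4.04 to 4.31 in males. KO females (4.62 to 8.63) and KO males (4.65 to 8.56) overlapped for Sult3a1. Male signal of Sult2a1, Sult2a2 and Sult2a5 and female signal of Cyp4a12a lay within the range of the negative controls. So did WT male signal of Slc22a26 and Sult3a1 and KO female signal of Cyp4a12b and Slco1a1. The sizes and ranks of all these genes are not exact. In all, 808 features passed, 411 higher in females and 397 lower (284 and 684 after quantile normalization, 163 and 515 among protein-coding genes). Slc22a26 lost its call in 10 of 12 fits that left out 1 mouse. Sult3a1 and Sult2a8 were not refitted in that way for this comparison. The count was 339, 246 and 420 without WT male 17, 23 or 33, 269 and 215 without WT female 25 or 27, 474 without KO male 18, 297 and 274 without KO female 13 or 69, and 15 with the poly-A covariate.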

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

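The tests of the macrophage and small nuclear RNA patterns, the poly-A covariate among them, and the splits with the genotype effect taken off were chosen after the result was seen; the other splits of the mice were set beforehand.

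Macrophage genes higher in KO. The list's median of 1.83 (bootstrap 95% interval over members 1.13 to 2.48) can be set against 3 technical explanations. A lower share of hepatocytes would raise every other cell type alike. The endothelial list had a median of -0.21 (-0.47 to 0.03), below that range, and of 0.026 with the poly-A covariate. Over its 10 genes above background the median was -0.28 (-0.67 to 0.76), against 2.48 (1.34 to 3.55) over 19 macrophage genes. Endothelial genes moved both ways, with Pecam1 at 1.14 and Cdh5 at 0.76 but Clec4g at -1.46 and Kdr at -0.63. These intervals are over genes, not mice. The endothelial list thus did not rise as the macrophage list did, which does not exclude a change in the shares of cells. More blood left in the KO livers stays open. The erythroid list had a median of 0.21 (-0.04 to 0.47), but only 2 of its 12 genes had no group within the range of the negative controls, so it decides nothing. The 4 features of adult haemoglobin genes, outside the list because each carries several symbols and chosen after the result was seen, were at 2.66, 2.11, 1.52 and 0.77, of which the first 3 passed (limma adjusted p = 0.0153, 0.0206 and 0.0398), and the neutrophil and platelet lists had medians of 0.88 and 0.36. With the poly-A spike level as a covariate the median was 2.32 and passed fry at an unadjusted threshold of 0.05. That level did not overlap between genotypes within either sex, so the fit extrapolates and cannot tell drift from genotype. Single calls ended as errors grew (Marco 6.27 ± 0.73 before and 7.55 ± 1.86 after, S100a8 8.30 ± 1.02 and 11.19 ± 2.45) or as the estimate shrank (Car3, outside the list, -4.82 ± 0.67 and -1.18 ± 1.15). A larger or altered macrophage population in KO liver and a change of expression in resident cells stay open beside such drift. Of the 32 genes, 3 are also in another list. The WT mean of 30 lay above the median signal of all features. That median is close to the negative control medians, so this does not show detection. Only 19 of the 32 had no group within the range of the negative controls. The highest KO signals, which do not rank amounts between probes, were those of Cd5l (14.1), Ctss (13.7) and Marco (13.4). Clec4f, a gene of resident Kupffer cells chosen after its value was seen, was at 0.21 ± 0.41 (adjusted p = 0.819).

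Small nuclear RNA and control features shifted with genotype. These lay outside the comparisons of genes: against WT, KO arrays differed by 0.14 for the negative control median, by -0.39 for the positive control median and by -0.86 for the poly-A spike mean. Of 927 small nuclear RNA features 444 were higher in KO and 0 lower by limma, with a median of 0.51, and of features without a named gene 1679 were higher and 396 lower, whereas of called protein-coding features 922 were higher and 2124 lower, although the median of all protein-coding features was 0.02. One shift of all log2 values of an array is excluded as the whole cause, since centring each array left a median of 0.44. Array medians lay close to the negative control medians. Centring on them therefore cannot exclude a scaling factor that acts on signal above background. Drift in RNA or labelling quality tracked by the poly-A spikes cannot be told apart from genotype for this pattern: with that covariate the median was 0.27 and did not pass fry at an unadjusted threshold of 0.05. A real difference in these transcripts also stays open.

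The interaction was called for 1 feature and, with a preset correlation, for 17 lists; 0 of 37 lists passed with an estimated correlation (smallest adjusted p = 0.13). The Rnu1b1 feature had an interaction of -1.08 ± 0.10 (limma adjusted p = 0.0386), with all female and all KO male arrays at the ceiling and WT males at 18.86, so the female difference is unknown and neither this estimate nor its p can be read as an interaction. By camera with a preset correlation, KO minus WT differences were less positive or more negative in females than in males for the lists of female-biased genes (median interaction -1.11), cytochrome P450 and xenobiotic enzymes (-1.06), pericentral hepatocytes (-0.91), cholesterol (-0.65), fatty acid and triglyceride synthesis (-0.48), the unfolded protein response (-0.44), bile acids (-0.44), neighbouring tissues (-0.38), fatty acid oxidation (-0.29), glycolysis and glycogen (-0.12), oxidative phosphorylation (-0.12) and nucleosides (-0.088). The opposite held for macrophages (0.97), inflammatory cytokines (0.30), endothelial cells (0.27), stellate cells (0.24) and the cell cycle (0.20).

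Other splits of the mice bear on whether chance can be excluded for each count. For KO against WT, 1 of 100 splits drawn from the 200 within sex, the real one with 6432 features, reached its own count, and the highest other was 342, so chance can be excluded. For females against males, 1 of 100 splits reached 808 and the highest other gave 4, so chance can be excluded. For the interaction 11 of 100 splits gave 1 feature or more, the highest other giving 249, but that count decides nothing: the splits exchange genotype separately in each sex, so an uneven exchange turns the genotype effect into an interaction. With the average genotype effect of each feature taken off first, 6 of 100 splits gave 1 feature or more and the highest other gave 7, so chance cannot be excluded. For the lists 18 of 100 splits gave 19 lists or more, with 25 as the highest other, so chance cannot be excluded for the number of lists called with the preset correlation. Within 1 sex only 10 splits exist, too few for a share under 0.05: in females 1 of 10 reached 4083, the highest other giving 1, and in males 1 of 10 reached 716, the highest other giving 0.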

How the results depend on the processing

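Of the alternatives, those with the poly-A spike covariate, protein-coding genes, the ceiling and the removal of KO male 19 and WT female 38 were chosen after the result was seen. Detection calls were not used, and 366 features reached the ceiling on at least 1 array. With the poly-A covariate 3 features were called for KO against WT, 74 in females, 0 in males, 5 for the interaction and 15 between the sexes; Slc29a3 was at -0.80 (adjusted p = 0.222), and of 159 called named genes 152 lost their call while 158 kept their sign. Igfbp2 turned to 0.091, and the lists of lysosome (0.23), autophagy (0.093), cholesterol (0.64) and endothelial cells (0.026) changed direction; the covariate differs between genotypes, which widens errors, and the cause was not tested further. Counts that moved by over 1.5 times were 3661 for KO against WT at 1.5-fold and 3918 with fewer, protein-coding features tested; 1853 for females fitted alone; and for males 1089 after quantile normalization, 1087 with array weights, 37 fitted alone and 408 protein-coding. The interaction count was 0 after quantile normalization, 4 centred, 12 without dim features, 0 with trend and robust variance, 0 with array weights, 11 with 1 feature per gene, 10 protein-coding and 0 without ceiling features; the cause was not tested. With an estimated correlation 0 lists were called, the correlations estimated here being 0.014 to 0.652 against a preset 0.01. Leaving out each mouse gave 4553 to 6599 features for KO against WT, 1581 to 4563 in females, 161 to 938 in males, 0 to 55 for the interaction, 215 to 1159 between the sexes, 18 to 23 lists and -0.98 to -0.88 for Slc29a3. Over all alternatives, 190 named genes gave 4299 values, of which 3793 kept direction and side of the threshold, 390 lost a call, 115 gained one and 1 reversed; 37 lists gave 888, of which 828 kept both, 40 lost a call, 16 gained one and 4 reversed. Of 159 called genes 131 stayed called without any single mouse, each gene being checked in 1 comparison only.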

Other observations

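The test of genes near Slc29a3 was set before its result was seen. Of 35 genes of the unfolded protein and integrated stress response 4 fell and 2 rose (8 and 2 over the list alone): Shmt2, a mitochondrial enzyme of serine metabolism, was at -1.62 ± 0.16, the transcription factor Atf5 at -0.59 ± 0.10 and Ddit4, an inhibitor of mTORC1, at 3.38 ± 0.71 (limma adjusted p = 0.015). Of 15 heat shock genes 3 fell (4 over the list alone), with the Hsp90 co-chaperones Stip1 at -1.28 ± 0.17 and Fkbp4 at -1.26 ± 0.23. Of 22 p53 and DNA damage genes 4 rose and 1 fell (8 and 4 over the list alone), with Btg2 at 0.90 ± 0.11 and Perp at -1.91 ± 0.19. Of 27 iron and haem genes 6 fell and 1, Hmox1 (3.44 ± 0.55), rose (8 and 1 over the list alone), with Uros, a step of haem synthesis, at -0.42 ± 0.07. Of 23 clock genes 6 fell and 3 rose (8 and 4 over the list alone). Among these Nfil3 was at 1.76 in females and 0.28 in males, Nr1d1 at -0.25 and -3.57, and, chosen after their values were seen, Arntl at 2.32 and 0.29 and Dbp at -2.67 and -1.60. The interaction did not pass for these 4 genes (limma adjusted p = 0.115, 0.287, 0.376 and 0.897). Signal of Nfil3 lay within the range of the negative controls in every group, so its sizes are not exact.

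With the poly-A covariate Ddit4 was at 6.18, Fkbp4 at -1.91, Ccne1 at 0.80 and Myc at 1.40. Of 39 cell cycle genes 3 rose (2 over the list alone), including Ccne1 (0.43 ± 0.08, adjusted p = 0.0777 after quantile normalization). Of 21 translation and ribosome genes 4 rose (7 over the list alone), including Rps9 (0.65 ± 0.10) and Rps4x (0.53 ± 0.09). Of 18 stem and progenitor markers 2 rose (2 and 1 lower over the list alone), Myc at 0.75 ± 0.21 and Procr at 0.33 ± 0.08, which lost their calls in 9 and 7 of 12 fits that left out 1 mouse. Camera with a preset correlation called the lists of heat shock as lower (adjusted p = 0.000228, 0.26 with an estimated correlation), the cell cycle as higher (1.98e-05, 0.457 with an estimated correlation) and translation as higher (0.0262, 0.51 with an estimated correlation, 0.0697 without WT male 33, 0.0694 without KO male 18 and 0.0561 without KO male 19). The others did not pass, with camera adjusted p = 0.188 for the unfolded protein response, 0.232 for p53, 0.0814 for iron and haem (0.0481 without WT female 25), 0.146 for the clock and 0.756 for stem markers. The poly-A spikes were lower by 0.86 in the same KO arrays.

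Passenger DNA from another strain around the targeted gene could give changed genes clustered near Slc29a3. Within 10 Mb on chromosome 10, 25 of 172 genes were called (14.5%), against 4289 of 30527 elsewhere (14.05%, one-sided Fisher exact p = 0.461), with 24.2 called genes predicted by chance. Called genes were thus about as frequent near Slc29a3 as elsewhere. With 24.2 predicted by chance, an excess of a few genes could not have been seen, so passenger DNA stays open. Among the 25, the nearby genes Pbld2 and Pbld1 had the smallest p, with -2.30 ± 0.24 and -2.19 ± 0.25, and were chosen after their values were seen.

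On the first principal component, which held 44.2% of the variance, KO females lay at 77.1 to 97.5 and WT males at -69.9 to -64.8. KO males lay at -3.56 to 32.5 and WT females at -53.3 to -10.3. KO male 19 (-3.56) was the KO mouse nearest to the WT mice, and WT female 38 (-53.3) was the WT female nearest to the WT males. WT female 25 (-10.3) was the WT mouse nearest to the KO mice.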
